A study of Mus musculus with 10 samples.

How the data were processed

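Dorsal root ganglia of 10 mouse samples at an age of 1 month were compared, 5 with a floxed Kif2a allele and cre driven by Avil (Kif2a_cKO) and 5 with the floxed allele alone (control). Groups and replicate numbers were taken from the sample labels. The labels state that polyadenylated RNA was purified and sequenced.

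Per the submitters' processing notes, cutadapt, STAR and DESeq2 were used with the mm10 genome, without versions. The read counter, the gene annotation, strandedness and read filters are not given in the sources used here. The authors deposited raw counts per gene symbol for each library, whole numbers, with at least 6 reads over the 10 libraries for every gene. The authors also deposited a normalized signal, the count divided by a size factor for each library. The deposited table gives a log2 fold change of the authors' own DESeq2 comparison, and whether it was shrunken is not stated. The deposited p-value and a false discovery rate stand beside it, the latter calculated with fdrtools per the file headers. The other deposited column is a yes or no flag for genes past the authors' thresholds on false discovery rate and a 1.5-fold change. Only the raw counts were used for the tests here, and the authors' comparison was set beside them. Because counts are summed over a gene, they cannot separate exons, isoforms or cell types, and reads shared between similar genes depend on the read counter.

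Library totals ran from 17506135 to 73031457 counts. Precision was taken from the spread between libraries. Gene symbols were matched to GENCODE release 21 for mouse (GRCm38) for position and biotype, and 97.6% matched.

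Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 17439 of 23923 genes and removed 6484. Libraries were scaled by TMM, with factors from 0.957 to 1.05, and a quasi-likelihood F test with robust dispersion was run on the group alone. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. The standard error of a log2 fold change was its size divided by the square root of F. Levels are CPM, counts scaled to a library of 1e6 with TMM factors, and log2 CPM used a prior count of 2. Single values and list scores were compared by a two-sided exact permutation test over all splits of the 10 libraries, whose smallest p is 0.00794. Across all tested genes 1217 had an unadjusted p under 0.05, against 872 by chance alone. With the mean level of a list of spinal cord genes as a covariate the number was 860 over the same genes. That fit, chosen after seeing the data, left no excess over chance. Its covariate was itself lower in Kif2a_cKO (mean log2 CPM 1.94 against 3.00 in controls), so it may take up part of a group difference. With the replicate number as a block, a planned fit, the number was 1499 over the same genes. With each library left out in turn the number ran from 801 to 1527.

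Named genes were chosen by a rule set before the data were examined, as were the gene lists, the tests and most of the alternatives. The rule takes Kif2a and Avil, then up to 10 called genes per direction with a mean of at least 1 CPM, then up to 4 called members of each list, or otherwise up to 2 of its most abundant members. Genes outside this rule were chosen after their values were seen: Mmp12, Nts, Map7, the members named as moving when adjusted over the list alone, and the genes named from the DESeq2 refit. The other uncalled members given for comparison were also chosen after their values were seen where they were not the most abundant of their list. Single-gene results of some list members are not reported here.

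The 45 gene lists covered neuron subtypes, injury, peptides, cytoskeleton, channels, receptors, glia, other cell types and general processes. Each was tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 45 lists. Of the 12 lists called, none was called with an estimated correlation (lowest adjusted p = 0.436) or by fry, which tests whether the genes of a list move one way on balance (lowest adjusted p = 0.169). fry's test for change in either direction called 5 lists. Called members are counted over all genes and adjusted over the list alone.

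Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, median-of-ratios scaling, library totals alone, no filter, a filter of at least 1 CPM in 5 libraries, other thresholds, the replicate number as a block, and leaving out each library in turn. A term for sex was not run because Y-linked transcripts were present in every library. Chosen after seeing the data were leaving out control replicates 1, 3 and 5, the spinal cord list score as a covariate, thinning all libraries to the smallest total, exact permutation of list scores, and removing the trend of log2 fold changes on transcript length and GC content (loess, span 0.5, 98.4% of tested genes with a value).

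The tools were tested on simulated data of the same size and spread. From the genes with a mean of at least 1 CPM, 100 were changed by 0.5 and 100 by 1 on the log2 scale. edgeR recovered 47% and 87% of them with 6 false among 140 calls, DESeq2 65% and 89% with 42 false among 196, and limma-voom 41% and 88% with 6 false among 135. These counts were drawn independently for each gene, without differences between libraries that many genes share. The rates therefore need not hold in the real data, and the recovery rates do not cover genes with a mean below 1 CPM, such as Mmp12. In simulated data with independent genes, which the real lists are not, a list raised by 0.25 was called by camera with either correlation and by fry, with 0 other lists called in each. Estimated correlations of the real lists reached 0.894, so this does not give the rate of false list calls in these data.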

Results

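Gene expression was measured by RNA sequencing of polyadenylated RNA from mouse dorsal root ganglia, the clusters of sensory neuron cell bodies that lie beside the spinal cord. Kif2a is a kinesin that takes microtubules apart at their ends. Cre recombinase driven by Avil, a gene active in sensory neurons, was combined with a floxed Kif2a allele in 5 samples, named Kif2a_cKO here. The other 5 samples carried the floxed allele without cre and are named control. All were taken at an age of 1 month, and the comparison asks which transcripts differ in the ganglion when Kif2a is targeted in sensory neurons. Because cre was present in 1 group only, the presence of cre and the deletion of Kif2a cannot be separated. The labels give replicate numbers and do not state that each sample is a separate animal, so p-values measure the spread between these samples.

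The total count per library ran from 17506135 to 34500320 in the controls and from 28686616 to 73031457 in Kif2a_cKO. Replicates of a group had a Pearson correlation of log2 CPM (counts scaled to a fixed library total) between 0.964 and 0.989. Counts of replicate pairs differed by more than sampling noise, with a lowest chi-square of 10.3 per gene, so each library was counted once. Of the 23923 genes deposited, 17439 had enough counts to be tested in edgeR.

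The total count of Kif2a was not detectably lower in Kif2a_cKO. Kif2a, on the minus strand of chromosome 13 from 106958996 to 107022126 (GRCm38), had 69.0 ± 4.44 CPM in Kif2a_cKO and 70.2 ± 8.61 CPM in controls (SD, n = 5 each). The log2 fold change was -0.02 (SE 0.087, edgeR adjusted p = 0.986), and its 95% interval ran from -14.4% to 13.2%. The value counts all exons and all cells of the ganglion together, and the labels do not say which exons were floxed, so it does not check the deletion. Avil, which encodes the actin-binding protein advillin (chromosome 10 from 127000709 to 127020994, plus strand), had 383 ± 55.0 CPM in Kif2a_cKO against 678 ± 149 CPM in controls (SD, n = 5 each). This log2 fold change of -0.82 (SE 0.156) missed the threshold in edgeR (adjusted p = 0.351) and passed it in DESeq2 (adjusted p = 0.000347) and in limma-voom (adjusted p = 0.0393). Control 3, at 437 CPM, lay within the Kif2a_cKO range, and without control replicate 3 the edgeR adjusted p was 0.0203.

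**Figure D1:**
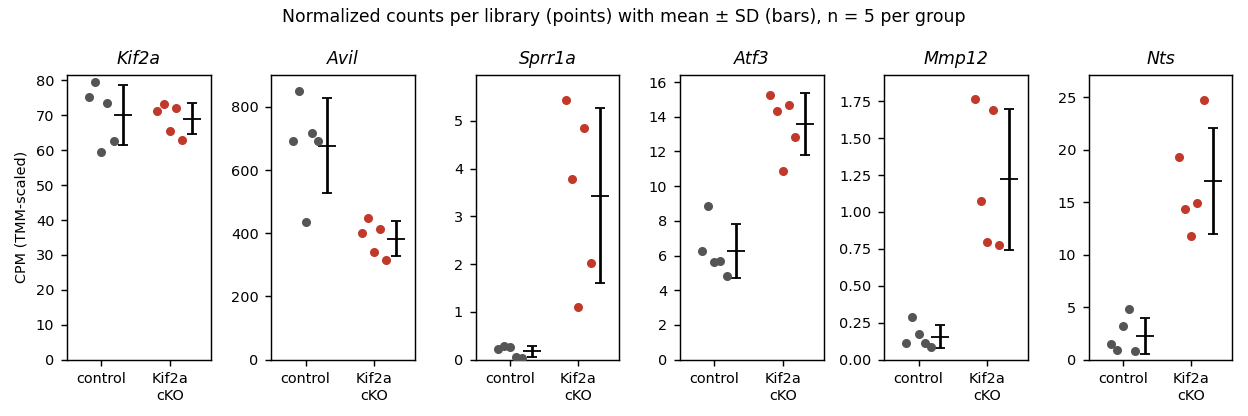
Normalized counts (CPM, TMM-scaled, linear axes from 0) of Kif2a, Avil, Sprr1a, Atf3, Mmp12 and Nts in each of the 5 control and 5 Kif2a_cKO libraries, with the mean ± SD beside the points. Kif2a had 69.0 and 70.2 CPM in Kif2a_cKO and control, whereas Sprr1a, Atf3, Mmp12 and Nts were higher in each Kif2a_cKO library than in any control.

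Sprr1a and Atf3, members of the axon injury and regeneration list, and Mmp12, which is not in that list, were higher in Kif2a_cKO. Sprr1a, a small proline-rich protein induced in injured neurons, rose 18.9-fold from 0.173 ± 0.121 to 3.44 ± 1.84 CPM (SD, n = 5 each; log2 fold change 4.24, SE 0.551). Atf3, a transcription factor induced by nerve injury and stress, rose 2.17-fold from 6.26 ± 1.54 to 13.6 ± 1.78 CPM (log2 fold change 1.12, SE 0.156). Mmp12, a matrix metalloproteinase best known from macrophages, rose 7.77-fold from 0.156 ± 0.080 to 1.22 ± 0.477 CPM (log2 fold change 2.96, SE 0.383). These 3 were the only genes called by edgeR, each with an adjusted p of 0.0453. edgeR called 0 genes lower, with 699 lower at an unadjusted p under 0.05, whereas DESeq2 called 24 lower and limma-voom 1. limma-voom called Atf3 and Mmp12 but not Sprr1a (adjusted p = 0.221). Mmp12 lay below the CPM limit for named genes and was chosen after its values were seen. Sprr1a lies on chromosome 3 from 92483952 to 92485895, Atf3 on chromosome 1 from 191170296 to 191218039 (both minus strand), and Mmp12 on chromosome 9 from 7344381 to 7369499 (plus strand). In all 3 genes the 5 Kif2a_cKO libraries lay above the 5 controls. The groups did not overlap in 204 of the tested genes (1.17%, against 0.794% by chance). The calls were close to the threshold: leaving out control 1, 4 or 5, or Kif2a_cKO 1, 2, 4 or 5 left 0 genes called in edgeR, with a lowest adjusted p between 0.0549 and 0.214 and between 885 and 1438 genes at an unadjusted p under 0.05. Without control replicate 2 edgeR called Atf3 and Mmp12, without control replicate 3 it called Avil alone, and without Kif2a_cKO replicate 3 it called all 3. With a stricter filter on low counts edgeR called 0 genes (1011 at an unadjusted p under 0.05), with an adjusted p of 0.0509 for Sprr1a and Atf3, and Mmp12 was not tested. With the replicate number as a block edgeR also called 0 genes (adjusted p of 0.0766 for Atf3, 0.0816 for Mmp12 and 0.0817 for Sprr1a). Without control replicates 1, 3 and 5, the controls with the most spinal cord transcripts, edgeR called 0 genes (604 at an unadjusted p under 0.05) and DESeq2 called 9. The 9 included Sprr1a and Atf3, and also mt-Atp6, whose counts lay almost all in control 2. Leaving out these controls was chosen after seeing the data.

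Of the 54 measured members of the axon injury and regeneration list, 2 rose, none fell and 52 were not called over all genes. Adjusted over the list alone, 3 rose, the third being Nts, which encodes neurotensin. Nts had 17.0 ± 5.08 CPM in Kif2a_cKO and 2.24 ± 1.71 CPM in controls (SD, n = 5 each; log2 fold change 2.98, SE 0.470), with an adjusted p of 0.309 in edgeR, 2.76e-05 in DESeq2 and 0.0268 in limma-voom. At an unadjusted p under 0.05, 7 members were higher and 1 was lower. Gap43 had a log2 fold change of 0.23 (SE 0.0987) and Gal, which encodes galanin, one of 0.46 (SE 0.207), both uncalled. As a list the injury genes were shifted up (median log2 fold change 0.05, mean 0.16, camera adjusted p = 0.0286), and the adjusted p was 0.604 with an estimated correlation. That call was also lost without control 4 or 5, or without Kif2a_cKO 1, 2 or 4 (adjusted p between 0.061 and 0.0965), and without control replicates 1, 3 and 5 together (adjusted p = 0.285) or with no filter on low counts (adjusted p = 0.0865). The median was between 0.020 and 0.026 without control 3 or 5 or Kif2a_cKO 1 or 2.

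Genes of cholesterol synthesis were higher as a group. All 24 list members were measured, and 21 had a log2 fold change above 0, with a median of 0.19 (camera adjusted p = 2.08e-07). The adjusted p was 0.436 with an estimated correlation. None of the 24 was called over all genes by edgeR, and 4 rose when adjusted over the list alone. Stard4, a sterol carrier, had 69.7 ± 6.38 CPM in Kif2a_cKO and 54.2 ± 1.36 CPM in controls (SD, n = 5 each; log2 fold change 0.36, SE 0.0696). DESeq2 called Stard4 over all genes (adjusted p = 0.00356). Mvd and Fdps, enzymes of the mevalonate pathway, had log2 fold changes of 0.33 (SE 0.0757) and 0.32 (SE 0.0898), and Tm7sf2, a sterol reductase, one of 0.25 (SE 0.0766). Hmgcs1, the most abundant member, had a log2 fold change of 0.06 (SE 0.102). The mean log2 CPM of the list was 6.73 ± 0.081 in Kif2a_cKO and 6.55 ± 0.044 in controls (SD, n = 5 each), and each Kif2a_cKO library lay above each control. A two-sided exact permutation test of that mean gave p = 0.00794, the smallest that 5 libraries against 5 can give, and 0.179 after adjustment over the 45 lists. In this test axon guidance genes had the same p. Of the 45 lists 4 had a p under 0.05 before adjustment and 0 after it. Acat2, an acetyl-CoA acetyltransferase outside the list, had 104 ± 12.8 CPM against 72.1 ± 4.42 CPM in controls (adjusted p = 0.155 in edgeR and 0.000234 in DESeq2), and was chosen after its values were seen.

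**Figure D2:**
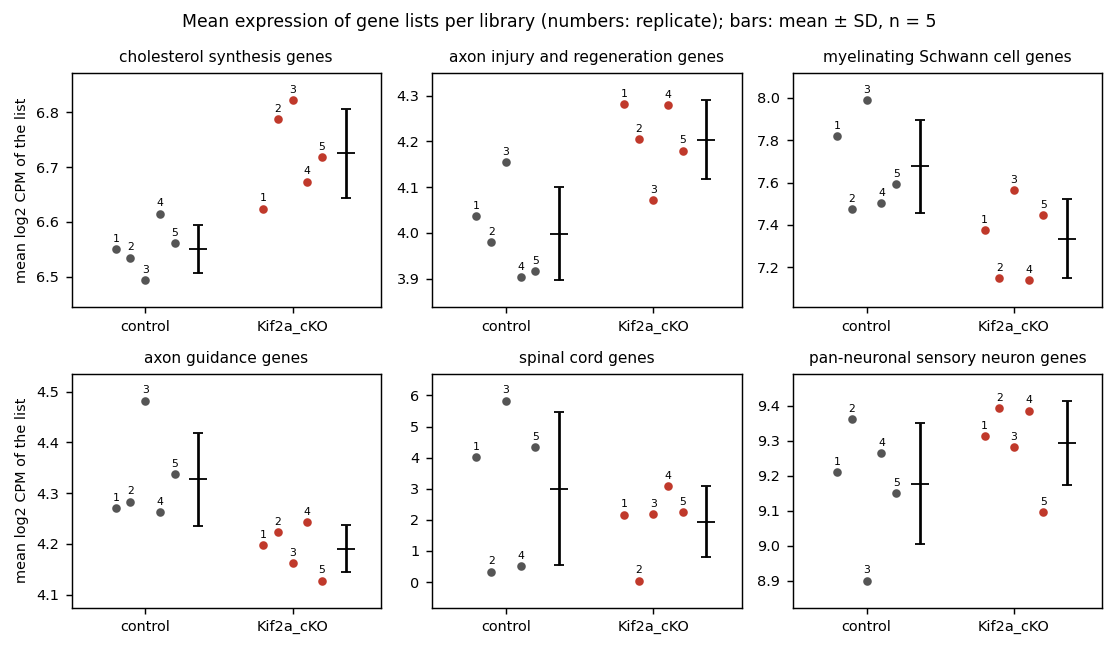
Mean log2 CPM of 6 gene lists in each library, with the replicate number above each point and the mean ± SD of each group beside the points; the axes do not start at 0. The cholesterol synthesis list was higher in each Kif2a_cKO library than in any control, and the spinal cord list was highest in controls 1, 3 and 5.

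Sensory neuron genes showed small shifts in both directions. The pan-neuronal list was shifted up (23 measured members, 21 above 0, median log2 fold change 0.16, camera adjusted p = 0.000458), with none called over all genes or adjusted over the list alone. The adjusted p was 0.944 with an estimated correlation. Its most abundant members were Nefm at 0.21 (SE 0.175) and Sncg at 0.18 (SE 0.0918). Low-threshold mechanoreceptor markers (16 measured, 14 above 0) had a median of 0.17 (adjusted p = 0.00231), and peptidergic nociceptor markers (19 measured, 16 above 0) one of 0.13 (adjusted p = 0.0345), each with no member called in either way. With an estimated correlation the adjusted p was 0.654 for the mechanoreceptor markers and 0.944 for the peptidergic markers. Without control replicate 3 alone the medians were 0.06 for the pan-neuronal list, 0.07 for the mechanoreceptor markers and 0.06 for the peptidergic markers, and the first 2 lists were called (adjusted p of 0.0168 and 0.0243). Without Kif2a_cKO replicate 2 the peptidergic median was 0.08. All 3 lists were uncalled without control replicates 1, 3 and 5, with medians of 0.00 for the pan-neuronal list, 0.07 for the mechanoreceptor markers and -0.02 for the peptidergic markers (adjusted p of 0.68, 0.339 and 0.559). The peptidergic call was also lost without control 1 or 3 or Kif2a_cKO 2 or 4 (adjusted p between 0.0644 and 0.268). It was lost as well with no filter (adjusted p = 0.0564), with the trend on transcript length and GC content removed (adjusted p = 0.0743) and with the spinal cord list score as a covariate (median 0.04, adjusted p = 0.326), the last 2 chosen after seeing the data. In control 3, which had the highest spinal cord list score, the pan-neuronal mean log2 CPM was 8.90, the lowest of the 10 libraries.

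Itch neuron markers were shifted down (13 measured, 11 below 0, median log2 fold change -0.23, camera adjusted p = 0.00174), and the adjusted p was 0.604 with an estimated correlation. Without Kif2a_cKO replicate 4 the median was -0.34. Adjusted over the list alone, Nppb and Osmr fell and Nts rose, while edgeR called none over all genes. DESeq2 called Nppb and Nts over all genes (adjusted p of 0.0305 and 2.76e-05), and limma-voom called Nts (adjusted p = 0.0268). Nppb, a natriuretic peptide of itch neurons, had 7.84 ± 0.851 CPM against 12.5 ± 3.09 CPM in controls (SD, n = 5 each), and Osmr, the oncostatin M receptor, 43.4 ± 1.92 against 54.6 ± 6.28 CPM. Sst, which encodes somatostatin, and Il31ra, the interleukin receptor of the same neurons, had log2 fold changes of -1.34 (SE 0.477) and -0.74 (SE 0.295) and were not called. Of the 21 measured neuropeptide genes, 3 rose and 1 fell adjusted over the list alone: Nts, Calca and Calcb up and Nppb down. Calca and Calcb, which encode CGRP peptides, had log2 fold changes of 0.31 (SE 0.0981) and 0.26 (SE 0.0846). The neuropeptide list had a median of -0.01 and was not shifted (camera adjusted p = 0.395). The lists of non-peptidergic, cold-sensing and proprioceptive neuron markers were not called either, with adjusted p values of 0.107, 0.836 and 0.945. Ret had a log2 fold change of 0.08 (SE 0.188), Trpm8 of 0.02 (SE 0.217) and Pvalb of 0.18 (SE 0.139).

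Genes of myelinating Schwann cells were lower. Of 26 measured members 25 had a log2 fold change below 0, with a median of -0.32 (camera adjusted p = 7.15e-12), and the adjusted p was 0.604 with an estimated correlation. None was called over all genes by edgeR, and Fa2h, a fatty acid hydroxylase of myelin lipids, fell when adjusted over the list alone, from 197 ± 16.9 to 139 ± 22.4 CPM (SD, n = 5 each). DESeq2 called Fa2h over all genes (adjusted p = 0.0129), also with the spinal cord list score as a covariate (adjusted p = 0.0389). The myelin genes Mbp, Prx and Pmp22 had log2 fold changes of -0.45 (SE 0.192), -0.35 (SE 0.104) and -0.15 (SE 0.148), all uncalled. The mean log2 CPM of the list was 7.34 ± 0.187 in Kif2a_cKO and 7.68 ± 0.221 in controls (SD, n = 5 each), and a two-sided exact permutation test gave p = 0.0317, or 0.357 adjusted over the 45 lists. Controls 1, 3 and 5, the controls with the most spinal cord transcripts, also had the highest values of this list, at 7.82, 7.99 and 7.59, and without control replicates 1, 3 and 5 the median was -0.13 (adjusted p = 0.00181). Satellite glia markers and non-myelinating and repair Schwann cell genes were not called (camera adjusted p of 0.947 and 0.692). The satellite glia median was -0.15 in all libraries and 0.19 without control replicates 1, 3 and 5 (adjusted p = 6.69e-05). Apoe, the most abundant satellite glia marker, had a log2 fold change of 0.23 (SE 0.1005).

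Spinal cord genes differed strongly between libraries of the same group. The spinal cord list, which holds oligodendrocyte, astrocyte and spinal neuron genes, had a median log2 fold change of -2.16, with all 18 measured members below 0 (camera adjusted p = 0.00057). The adjusted p was 0.944 with an estimated correlation, and no member was called in either way. Its mean log2 CPM was 4.01, 5.83 and 4.33 in controls 1, 3 and 5, 0.33 and 0.50 in controls 2 and 4, and between 0.05 and 3.08 in Kif2a_cKO. Its most abundant members were Mobp, a myelin protein of oligodendrocytes, with 136 ± 84.9 CPM in Kif2a_cKO and 398 ± 430.2 CPM in controls, and Slc1a2, an astrocyte glutamate transporter, with 25.7 ± 16.4 and 96.6 ± 122 CPM (SD, n = 5 each). Mog, an oligodendrocyte surface protein chosen after its values were seen, had 2.93 ± 2.17 CPM in Kif2a_cKO and 26.1 ± 34.1 CPM in controls. Without control replicates 1, 3 and 5 the list was higher in Kif2a_cKO, with a median of 1.78 (adjusted p = 2.34e-05). Without control replicate 3 its median was -1.19 and its adjusted p was 0.181, and without Kif2a_cKO replicate 2 it was 0.0532. In the DESeq2 fit 12 genes were called lower with a log2 fold change below -1, and all were highest in controls 1, 3 and 5. They included Slc18a3, the vesicular acetylcholine transporter of motor neurons (4.39 ± 5.67 CPM in controls, 0.213 ± 0.187 CPM in Kif2a_cKO), and the cilium gene Cfap45 (1.85 ± 1.602 against 0.322 ± 0.140 CPM), neither of which edgeR called. These genes were chosen after their values were seen.

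Axon guidance genes were shifted down, with 40 of 57 measured members below 0 and a median log2 fold change of -0.10 (camera adjusted p = 0.00508), and the adjusted p was 0.436 with an estimated correlation. None was called over all genes by edgeR, and 1 fell adjusted over the list alone: Plxnb1, a semaphorin receptor, at 33.3 ± 2.99 CPM against 46.3 ± 8.10 CPM in controls (SD, n = 5 each). DESeq2 called Plxnb1 over all genes (adjusted p = 0.0386). Sema3b, the most abundant member, had a log2 fold change of -0.35 (SE 0.161). The call was lost without Kif2a_cKO replicate 5 (adjusted p = 0.0637) and with the trend of the fold changes on transcript length and GC content removed (adjusted p = 0.161). Of 53 tubulin and microtubule regulator genes, none was called over all genes by edgeR and Map7, a protein that binds microtubules and recruits kinesin, rose adjusted over the list alone. Map7 had 44.6 ± 12.2 CPM in Kif2a_cKO and 22.7 ± 3.64 CPM in controls (SD, n = 5 each; log2 fold change 0.97, SE 0.179), higher in each Kif2a_cKO library than in any control, with an adjusted p of 0.351 in edgeR and 0.000282 in DESeq2. The list was not shifted (median 0.05, camera adjusted p = 0.0843), and Tubb3 and Map1b had log2 fold changes of 0.17 (SE 0.123) and 0.17 (SE 0.171). None of the 38 measured kinesins other than Kif2a was called, and their list was not shifted (median -0.03, adjusted p = 0.599). Kif5a had a log2 fold change of -0.11 (SE 0.111) and Kif1a of 0.00 (SE 0.129).

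Nuclear-encoded oxidative phosphorylation genes (47 measured, median log2 fold change 0.09, camera adjusted p = 0.000122), cytosolic ribosomal protein genes (49 measured, median 0.10, adjusted p = 0.00057) and heat shock genes (18 measured, median 0.11, adjusted p = 0.00866) were shifted up, with no member called in either way. With an estimated correlation the adjusted p was 0.944, 0.944 and 0.92. Hspa8, a constitutive chaperone, had a log2 fold change of 0.25 (SE 0.151). Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.17 with transcript length and -0.18 with GC content. For single libraries against the mean of all libraries, these correlations were -0.19 and -0.39 in Kif2a_cKO 5 and -0.21 and -0.03 in Kif2a_cKO 3. They were 0.07 and 0.005 in Kif2a_cKO 1, 0.05 and 0.19 in Kif2a_cKO 2, and -0.02 and 0.04 in Kif2a_cKO 4. The trend of the log2 fold changes was therefore not shared by all Kif2a_cKO libraries. With that trend removed, an alternative chosen after seeing the data, the oxidative phosphorylation and ribosomal medians were 0.03 and 0.04 and the lists were not called (adjusted p of 0.11 and 0.129), while the heat shock list was (adjusted p = 0.00635). The oxidative phosphorylation median was 0.04 without Kif2a_cKO replicate 5 (adjusted p = 0.0439) and 0.13 without Kif2a_cKO replicate 2. The ribosomal call was also lost without Kif2a_cKO replicate 5 (median 0.01, adjusted p = 0.546), with a median of 0.06 without control replicate 5, and the heat shock call without Kif2a_cKO replicate 3 or 4 (adjusted p of 0.0878 and 0.0781) or without control replicates 1, 3 and 5 (adjusted p = 0.655), with a median of 0.07 in the first 2 cases and without control replicate 3.

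The other 33 of the 45 lists were not called, with camera adjusted p values between 0.0843 and 0.947. Sodium, potassium and calcium channel genes and the receptor lists were among them. Scn10a and Scn11a had log2 fold changes of 0.03 (SE 0.183) and -0.08 (SE 0.211), and Piezo2 of 0.06 (SE 0.185). Macrophage genes had a median of 0.02 (adjusted p = 0.644), and Cd74 a log2 fold change of 0.21 (SE 0.167). Of 11 measured lymphocyte genes Cd4 rose adjusted over the list alone (log2 fold change 0.89, SE 0.249), and the list was not shifted (adjusted p = 0.156). Among immediate early genes Atf3 rose and 23 were not called over all genes. In 9 of the 45 lists, all uncalled, the median, the mean and the test differed in sign.

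The authors' deposited table of their own DESeq2 comparison marks 31 genes as past its thresholds, 12 higher and 19 lower in Kif2a_cKO. The header names a 1.5-fold change and a false discovery rate (FDR) without its threshold; the highest FDR among the 31 in the authors' deposited table was 0.0469. Of these, 21 were tested in edgeR, all 21 with the same direction, and 3 were called: Sprr1a, Atf3 and Mmp12. The edgeR fit used the counts deposited with that comparison and the same groups, so the shared direction is not independent evidence. A DESeq2 refit of the counts called 39 genes, 15 higher and 24 lower, of which 27 were among the 31. Besides the genes above, the refit called Adgb, Gpr119, Calhm4 and Csf2rb2 higher (adjusted p of 0.0157, 0.0141, 0.0093 and 0.0305), and Creb3l2, Hipk2 and Fam107a lower (adjusted p of 0.00356, 0.0292 and 0.0305), all chosen after their values were seen. The 31 genes of the authors' deposited table included the mitochondrial genes mt-Co3 and mt-Atp6. mt-Co3 had 21663 counts in Kif2a_cKO 4 and 0 in the other libraries, and mt-Atp6 had 352 counts in control 2, 1 in control 3 and 0 elsewhere. In the edgeR fit both were removed by the filter on low counts.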

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

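All tests of explanations in this part were chosen only after the result was seen, apart from the counts over other splits of the libraries. The fits leaving out each library in turn were planned, but their use as a test for a wrong label was not.

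The 12 genes that DESeq2 called lower with a log2 fold change below -1, Slc18a3 and Cfap45 among them, had a median of -2.87 in an edgeR fit without the filter, and 3 controls, 1, 3 and 5, had the highest level of each of the 12. These controls also had the highest scores of the spinal cord list, whose most abundant genes, Mobp and Slc1a2, had 398 and 96.6 CPM in controls on average, so spinal cord tissue in them is a candidate explanation. Without them the median was -0.67, but leaving out the libraries in which genes are highest shrinks a fall whatever its cause, so this stays open. With the spinal cord list score as a covariate the median was -1.94 and 2 of the 12 genes were still called by DESeq2, so whether the fixed list tracks all such tissue is open too. An effect of the genotype as the whole cause is argued against for these genes. The controls share a genotype, yet controls 1, 3 and 5 lay above controls 2 and 4 in each of the 12. The spinal cord list split in the same way, with scores of 4.01, 5.83 and 4.33 against 0.33 and 0.50. A smaller effect of the genotype cannot be told apart. Both remaining controls lay above every Kif2a_cKO library in 4 of the 12 genes, at a median count of 7 in those controls.

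Kif2a itself was not lower, although Kif2a was the targeted gene. A single mislabelled library that hides a fall is argued against as the cause. With each library left out in turn the log2 fold change stayed between -0.09 and 0.01 (edgeR adjusted p of at least 0.9). The lowest bound of the 95% intervals was -0.29, a change of -18.0%. A swap between a control and a Kif2a_cKO library was not tested. Because the total count does not check the deletion, these fits do not check the labels either. Reads from undeleted exons and from cells without cre could hide a loss, and the lower bound of the 95% interval, -14.4%, still allows a fall; a total count per gene cannot separate exons or cells, which keeps this open. Whether the deletion took place was not testable in these counts, and no other biological explanation was tested.

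Myelinating Schwann cell genes had a median log2 fold change of -0.32. The trend of fold changes on transcript length and GC content is argued against as the whole cause, since the median was -0.30 with the trend removed. Central myelin from spinal cord tissue in part of the controls may contribute. The median of 12 peripheral myelin genes, all also members of fixed lists, was -0.25. Its interval of -0.32 to -0.11 came from resampling the 12 genes, which are not independent, and leaves out the spread between libraries. The interval includes the bound of -0.16 set for this explanation, which cannot be told apart. A two-sided exact permutation test of the mean log2 CPM of these genes gave p = 0.103. Without controls 1, 3 and 5 the list median shrank to -0.13 while the peripheral median was -0.27 (interval over genes -0.34 to -0.098, again with the bound inside). With the spinal cord score as a covariate the list median was -0.24 (camera adjusted p = 3.21e-10 at the preset correlation). That score is the mean of the spinal cord list, so the shift of that list to -0.01 was fixed in advance. It does not show that central myelin was removed. Whether central myelin is a part or the whole of the cause stays open. Less nerve or fewer Schwann cells in Kif2a_cKO stays open, with a median of -0.015 over non-myelinating and repair Schwann cell genes whose members went both ways.

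Other splits of the 10 libraries bear on the counts. For edgeR 3 of 100 splits, the real one included, called at least 3 genes, and the highest other split called 6. This share lies under the bound of 0.05 set beforehand. Not every possible split was run and other splits called more genes, so the count alone does not exclude chance. The other splits that called as many each put replicates 1 and 2 of both groups together. For DESeq2 10 of 40 splits called at least 39 genes, and the highest other called 721, so chance is not excluded. That split set controls 1 and 2 with Kif2a_cKO 1, 2 and 4 against the rest. So many calls point to a structure of the samples, and which structure was not tested. The widest gap in the leading numbers of the sample titles separates replicates 1 and 2 of both groups from the others. The labels do not say what this gap means. A split with 705 DESeq2 calls did not put these replicates together. For the lists 48 of 100 splits called at least 12, the highest other 28, so chance is not excluded.

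Single libraries stood apart from the rest of their group by Dixon's ratio, the gap to the nearest library divided by the range, in 13 of 216 groups of 5, where chance gives about 1 in 20 groups, or 10.8. Kif2a_cKO 4 had 73031457 counts against 34417166 in the next library (ratio 0.871). In Kif2a_cKO, Gal was lowest in replicate 1 (0.728). In control 3, Plxnb1 was highest (0.903), and Nefh (0.81), Tubb3 (0.772) and Calhm4 (0.719) were lowest. Among list scores, Kif2a_cKO 5 was lowest for actin and growth cone regulators (0.76) and highest for macrophage (0.793), fibroblast and matrix (0.733) and cell cycle genes (0.728). Control 3 was highest for mitochondrially encoded genes (0.747). The list of Y-linked genes and Xist was lowest in control 4 (0.788) and highest in Kif2a_cKO 5 (0.716). A pair of mitochondrial genes left out of the edgeR test by the filter on counts had a signal in single libraries: mt-Co3 with 21663 counts in Kif2a_cKO 4 and 0 elsewhere, and mt-Atp6 with 352 counts in control 2 and 1 in control 3.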

How the results depend on the processing

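Alternatives chosen only after seeing the data were leaving out control libraries 1, 3 and 5, the spinal cord score as a covariate, thinning, exact permutation of list scores and removing the length and GC trend. Over all alternatives the Kif2a log2 fold change stayed between -0.15 and 0.01 (leave-one-out -0.09 to 0.01) and was not called (adjusted p between 0.9 and 1).

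The number of genes called by edgeR, 3, was 0 with the stricter filter (1011 at an unadjusted p under 0.05, lowest adjusted p 0.0509) and 0 without control libraries 1, 3 and 5 (604, lowest 0.209), where fewer libraries were tested. It ranged from 0 to 3 with each library left out in turn. DESeq2 called 39 genes, 9 without control libraries 1, 3 and 5, and 32 with the score as a covariate. The 9 included mt-Atp6, and the 32 included mt-Atp6 and mt-Co3, whose counts lay almost all in a single library. The 32 also included Olfr1306, Mug2, Gm48770, Gm49963 and AC158774.1, at log2 fold changes of 13.4 to 13.5. limma-voom called 4, the other scalings 3 each, no filter 2, thinning 2 and the covariate in edgeR 3. Sprr1a was not called with no filter (adjusted p = 0.056) or with the covariate in edgeR (adjusted p = 0.0535), where Avil was called instead (adjusted p = 0.0412). Where not stated, the cause was not tested.

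With the replicate number as a paired term (replicate block), edgeR called 0 genes (1499 at an unadjusted p under 0.05, lowest adjusted p 0.0766), 15 lists were called, and the Kif2a log2 fold change was -0.02. Equal numbers correlated across groups by 0.177, 0.367, 0.140, -0.147 and 0.252. The value for replicate 4 was negative, whereas 7 of 10 samples correlated best with their own number. The leading numbers of the sample titles put each control directly beside the Kif2a_cKO sample of the same replicate number. That order goes with pairing, but the labels do not say what the leading numbers stand for. Pairing of the samples by number is therefore possible and neither shown nor excluded.

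Of the 12 lists called, 0 were called with an estimated correlation, 0 by fry and 0 by exact permutation of list scores; leave-one-out gave 11 to 17 and the length and GC trend removed 9. Without control libraries 1, 3 and 5 the median reversed to -0.019 for peptidergic markers, 1.78 for spinal cord genes, 0.19 for satellite glia markers and 0.068 for ionotropic receptors. Over 990 list values 884 stayed on their side of the threshold, 63 lost and 39 gained a call, and 4 reversed, of which the peptidergic list was uncalled after reversing; of the 884, 764 kept their sign and 120, uncalled, had the other sign. Over 3091 values of 141 named genes 3001 stayed on their side of the threshold, 2739 of them with the same sign and 262, uncalled, with the other, while 38 lost and 52 gained a call. The authors' deposited table holds 31 genes past its thresholds and 46 on an FDR under 0.05 alone. A sex term was not run, since Y-linked transcripts were present in every library. After thinning to the smallest total, Sprr1a and Mmp12 were called (adjusted p = 0.0259 each) and Atf3 was not (log2 fold change 1.05, adjusted p = 0.0656).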

Other observations

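The tests of explanations and the added marker lists in this part were chosen only after the result was seen. So were the fits without control replicates 1, 3 and 5 and those with the spinal cord list score as a covariate. The fits of all libraries without a covariate and those leaving out each library in turn were planned.

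Ecel1, a protease induced in injured neurons, had 4.42 ± 0.780 CPM in Kif2a_cKO and 4.01 ± 4.40 CPM in controls (SD, n = 5 each; log2 fold change 0.12, SE 0.652). It was called by DESeq2 with the spinal cord list score as a covariate (log2 fold change 1.43, adjusted p = 0.0389) and without control replicates 1, 3 and 5 (2.55, adjusted p = 1.2e-08), and was not called by DESeq2 with all libraries and no covariate. edgeR did not call it in either setting (adjusted p of 0.924 with the covariate and 0.209 without these controls). Marker lists written after the data were seen had medians of -1.67 for ependymal cells, -2.48 for oligodendrocytes, -1.85 for astrocytes and -2.22 for motor neurons and spinal interneurons. Without control replicates 1, 3 and 5 the medians were 0.22, 1.65, 1.21 and 1.23, and two-sided exact permutation tests over all libraries gave p = 0.159, 0.286, 0.262 and 0.413. Of the 10 oligodendrocyte genes 6 were also in fixed lists, as were 3 of the 9 astrocyte genes, 7 of the 10 spinal neuron genes and 0 of the 16 ependymal genes.

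Avil was lower in Kif2a_cKO, with a log2 fold change of -0.82. Fewer sensory neurons are argued against, since the median of the pan-neuronal list was 0.16; it was 0.06 without control replicate 3 and 0.00 without control replicates 1, 3 and 5, where the Avil log2 fold change was -0.96 and -1.03. A candidate explanation is that the cre insertion disables 1 copy of Avil, which would give a log2 fold change of -1 in heterozygous cells; the 95% interval of -1.18 to -0.46 includes it. The labels do not say how cre was inserted.

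Of the 5 tested genes within 500 kb of Kif2a, Ipo11 (log2 fold change 0.36) and Dimt1 (-0.47) had an unadjusted p under 0.05 in edgeR, and both were called by DESeq2. Dimt1 (chromosome 13 from 106947127 to 106960224, plus strand) overlaps the end of Kif2a on the other strand. An effect of the recombined locus on its neighbours may be involved, but 6.12% of 784 windows with as many genes held as many, so it cannot be told apart from the frequency elsewhere.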
